A study of Escherichia coli str. K-12 substr. MG1655 with 2 samples.

How the data were processed

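*E. coli* cells derived from the laboratory strain MG1655 were grown in M9 medium with 2 g/L glucose at 37 °C to an optical density near 0.5, with 1 g/L arginine or without it, per the labels' protocols. The protocols describe cross-linking with 1% formaldehyde for 30 min, shearing to 200 to 400 bp, immunoprecipitation with an antibody against the myc tag and λ exonuclease digestion. A mock immunoprecipitation that the protocols mention was not used here, so that enrichment is given over the local background of the same library and not over a control. Per the labels, each of the 2 samples holds replicates 1 and 2 together. The files carry no replicate field, and each condition was treated as 1 pooled library.

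The deposited files give a signed score per chromosome position and strand. As tested on the files, its size is a whole number of read 5′ ends that start at that position, and its sign is negative on the minus strand in every row. The score is not scaled to depth in the deposited files, and copies of the same molecule appear to be counted each time, since up to 158491 read ends lie at 1 position. Per the submitters' processing notes, CASAVA 1.4 was among the tools. The aligner, the filters and the treatment of reads with several matches are not given in the sources used here. Reads in repeated sequence may therefore be missing or misplaced, and amplification raises single positions. Reads without a chromosome, 55 with arginine and 36 without, were left out.

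The chromosome is named NC_000913 in the files, without a version. The gene table at hand belongs to assembly ASM584v2 and lists 4 genes that end beyond the highest position in the files, so it was taken to describe another version. For this reason no gene was assigned to a region, and comparisons with known ArgR target genes were not made. The search for ARG boxes was not made either, because no genome sequence was used here.

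Regions were called in each library with the same rule. Read ends were summed in windows of 200 bp moved by 50 bp. A window was kept where both strands together reached at least 5 times the median window within 10 kb on each side, and each strand at least 3 times its own such median. Kept windows within 200 bp were merged, and a region's fold is that of its highest window. Regions of the 2 libraries were called shared at an overlap of at least 1 bp, and the overlap was compared with 100 shifted sets. The ratio between conditions was formed from the read ends of each region in the union of both sets, after scaling by the median background window of each library (136 read ends with and 135 without arginine). Alternatives were the total number of read ends and the number outside the regions. Intervals of ratios are exact conditional binomial intervals, and those of shares are Clopper-Pearson intervals. Each covers counting error only, and the intervals are narrow because the strong regions hold many read ends. No test across samples was made, because there was 1 library per condition.

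The distance between strands was measured from the top plus-strand to the top minus-strand position within 100 bp of the summit, and in the whole region for the positions of single regions and the counts of shared positions given in the text. The strand cross-correlation was averaged over regions, with strands of different regions paired for comparison. The regions named in the text are the 10 with the highest fold in either library and the 5 with the largest ratio in each direction, a rule fixed before the data were examined. Other regions are named as chosen after their values were seen. The part of the rule that names known ArgR targets could not be applied. The fold limits of 20 and 200 used to describe strong regions were chosen after the data were seen.

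The region rule was tested on simulated data with 200 planted sites on each library's background. In the simulated library with arginine it found 0 of 40 sites at 3-fold, 39 of 40 at 6-fold and 40 of 40 at each of 8-, 15- and 30-fold, with 3 regions at no planted site. In that without arginine it found 0 of 40 at 3-fold and 40 of 40 at each of the higher folds, with 0 regions at no planted site. The median recovered distance between strands was 92 bp in both, for a planted distance of 92 bp. Background positions were drawn singly from outside the called regions, so clusters of read ends were not kept. Regions at no planted site were therefore unlikely from the outset, and their number does not give that in the data. The planted sites had even strands and 1 distance, unlike many regions of the data. Other fold limits, window sizes, backgrounds, strand requirements, scalings, a cap on single positions and thinning of the deeper library were tried as alternatives. The calculations used Python 3.11.15 with numpy 2.4.6 and scipy 1.17.1.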

Results

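ChIP-exo profiles of the arginine repressor ArgR were compared between *Escherichia coli* K-12 MG1655 cells grown with 1 g/L arginine in the medium and cells grown without it. ArgR is a transcription factor that uses arginine as its corepressor and binds palindromic operators, called ARG boxes, at genes of arginine synthesis and transport. In ChIP-exo, λ exonuclease trims the immunoprecipitated DNA from its 5′ ends until it meets the cross-linked protein, so the 5′ ends of the reads mark the borders of the protected DNA on each strand. The series title gives the question as the architecture of DNA binding by the repressor inside the cell. There was 1 library per condition, in which the 2 replicates named in the title were pooled, so that no spread between replicates could be measured and no test across samples was made. The library with arginine held 12214933 read ends at 798083 positions, or 15.3 per occupied position. The library without arginine held 8627527 read ends at 1389169 positions, or 6.21 per occupied position. All intervals below are 95% intervals for counting error only, since reads copied from 1 molecule during amplification are not independent. Positions are those of the deposited files on the chromosome NC_000913, whose version the files do not name, and no gene was assigned to a region.

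With arginine, 490 regions of the chromosome were bound, with a signal at least 5 times the local median on both strands together and at least 3 times on each strand. The strongest region, 2945851–2948400, reached 2586 times the local median in its highest 200 bp window and held 1137280 read ends. The next, 3315451–3317700, reached 2378 times the local median with 1005258 read ends. The regions 28101–30250, 2557551–2558900, 4151701–4153800 and 3295801–3296700 followed at 1249, 1212, 1117 and 1109 times the local median. A few regions took a large part of the signal: the 2 regions with the most read ends held 17.5% of the library and the 10 with the most held 37.3%. Most regions were far weaker, with a median fold of 9.02, and 107 of the 490 reached a fold of 20. The regions covered 194750 bp, or 4.20% of the chromosome, and held 61.7% of all read ends (Clopper-Pearson interval 61.66–61.72%), a mean of 38.7 read ends per bp.

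Without arginine, 206 regions were bound under the same rule. The strongest were again 2945851–2948400 at 1387 times the local median and 3315451–3317700 at 1283 times, followed by 4151701–4153800 at 1045 times and 2557551–2558900 at 834 times. The 2 regions with the most read ends held 13.7% of the library, and the 10 with the most held 35.6%. A fold of 20 was reached by 47 regions. The regions covered 92350 bp, or 1.99% of the chromosome, and held 50.1% of all read ends (Clopper-Pearson interval 50.04–50.1%), a mean of 46.8 read ends per bp. Over the union of both sets, 510 regions chosen after the data were seen, the shares were 62.3% with and 53.5% without arginine.

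Nearly all regions bound without arginine were also bound with it. Of the 206 regions without arginine, 185 overlapped a region with arginine, against a mean of 17.8 and a highest value of 25 when 1 set was shifted along the chromosome 100 times. In the other direction, 184 of the 490 regions with arginine overlapped a region without it, 306 were called only with arginine, and 21 only without. The strand requirement set part of this difference: 90 of the 306 regions had a fold of at least 5 in the library without arginine and were left out there by the requirement on each strand, as were 14 of the 21 with arginine. The strongest sites were shared: 18 of the 20 regions with the highest fold were the same in both libraries. Of the 24 regions that reached a fold of 200 in either library, 23 were called in both. The exception, 2466951–2468500, was named after its values were seen. It had a fold of 290 with and 62.0 without arginine, with only 8.54% and 10.4% of its read ends on the plus strand. The 306 regions called only with arginine were mostly weak, with a median fold of 7.41, and the highest window that the library without arginine had within them reached a median fold of 3.98. The numbers of regions depended on the rule: with and without arginine there were 1113 and 597 at a fold of 3 with at least 2 on each strand, and 223 and 97 at a fold of 10. Windows of 100 bp gave 916 and 338, and no requirement on the strands gave 1173 and 749.

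**Figure D1:**
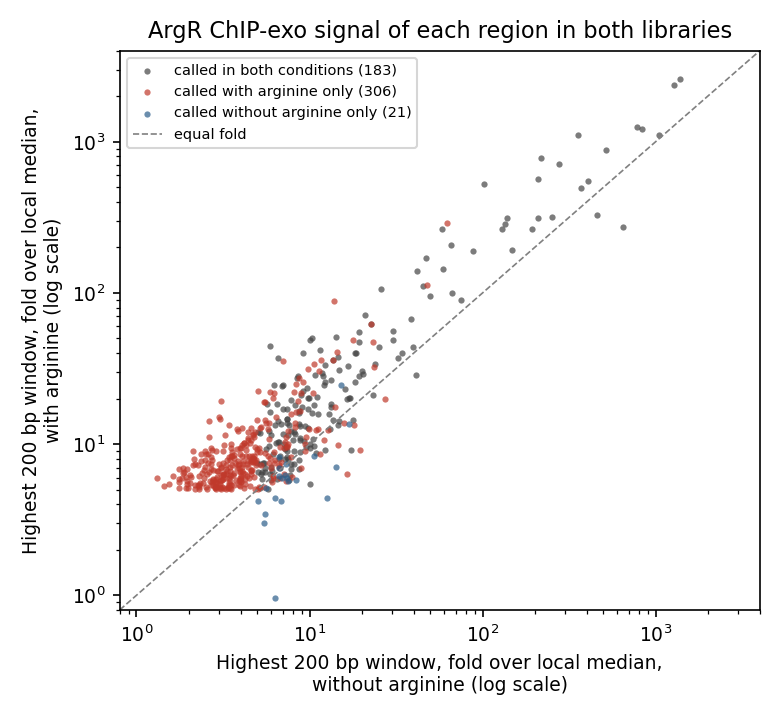
Each point is 1 of the 510 regions, with the fold of its highest 200 bp window over the local median in the library without arginine (x axis, log scale) and with arginine (y axis, log scale). Grey points (183) were called in both libraries, red points (306) only with arginine and blue points (21) only without, and the dashed line marks equal fold.

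Signal at the bound regions was higher with arginine under the main scaling, and the excess differed widely from region to region. With each library scaled by its median background window, 449 of the 510 regions were higher with arginine and 61 were higher without, with a median log2 ratio of 0.76 (quartiles 0.35 and 1.29). A ratio of at least 2 in favour of arginine was seen at 188 regions, and in the opposite direction at 4. These numbers were 79 and 12 with total scaling, and 146 and 5 with scaling outside the regions. Scaling by the total number of read ends shifted every log2 ratio by -0.49, which left 351 regions higher with arginine and 159 higher without, and a median of 0.26. Scaling by the read ends outside the regions shifted them by -0.19 and gave 419 and 91 regions. Of the 510 regions, 306 were called only with arginine and 21 only without. The excess with arginine therefore follows in part from how the set was chosen. Among the 183 regions called in both libraries the median was 0.58, with 157 regions higher with arginine and 26 higher without. With total scaling it was 0.09, with 107 and 76. These ratios compare the 2 libraries and have no replicate check.

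Among the strongest regions, the ratio between the conditions ranged widely under the main scaling. Over the 10 regions with the highest fold, the log2 ratio ran from -0.18 to 1.78. With single positions capped at the same height in both libraries, an alternative added after seeing the data, it ran from -0.069 to 0.64. Such a cap saturates the strongest positions and draws ratios toward 1. The top region 2945851–2948400 was 1.77 times higher with arginine (1.77–1.78), and 3315451–3317700 was 1.79 times higher (1.78–1.79). With that cap their log2 ratios fell to 0.057 and 0.14. The region 3487351–3488900 was 1.69 times higher (1.68–1.70). By contrast, 3295801–3296700 was 3.43 times higher (3.40–3.46), 2087101–2088550 was 3.37 times higher (3.34–3.41) and 3382151–3383100 was 2.62 times higher (2.60–2.65). These 6 regions were also higher with arginine under both other scalings. The regions 28101–30250 and 2557551–2558900 had ratios of 1.38 and 1.27, which turned to log2 values of -0.027 and -0.14 with total scaling. The region 4151701–4153800 held 456615 read ends with and 440398 without arginine, a ratio of 1.03 (1.02–1.03), which fell below 1 with both other scalings and with that cap. The region 4475401–4477100 was lower with arginine, with 345261 against 387641 read ends and a ratio of 0.884 (0.880–0.888). The drop was larger in its highest 200 bp window, the same in both libraries, where the log2 ratio of the read ends was -0.54. The fold of that window was 273 with and 651 without arginine, a wider gap because the local median was higher with arginine. With that cap the log2 ratio of the whole region was 0.24.

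The 5 largest ratios in each direction lay at weaker regions, with a fold of at most 44.5 in either library. The 5 largest in favour of arginine were at 570501–570900 (7.35, interval 6.91–7.83), 2782851–2783050 (6.61), 2993351–2993700 (6.01), 567901–568250 (5.82) and 4220101–4220750 (5.60). The first of these rose from a fold of 5.93 without arginine to 44.5 with it. The largest in the other direction was at 364001–364250, with 739 read ends without arginine and 104 with it, a ratio of 0.140 (0.113–0.172). Its fold was 6.28 without arginine and 0.952 with it. The other 4 in this direction were 169701–170050 (0.334), 3114801–3115150 (0.464), 1151201–1151400 (0.491) and 1347451–1347700 (0.518). Among them, 3114801–3115150 was called only with arginine, although its fold was 9.13 with and 19.7 without. It was left out without arginine by the requirement on each strand, with 91.5% of its read ends there on the plus strand. All 10 of these regions kept their direction under each scaling and with either cap on positions.

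In most bound regions the top minus-strand position near the summit lay downstream of the top plus-strand position (322 of 490 with and 142 of 206 without arginine). It lay upstream in 168 and 64 regions. A few preferred distances were seen in the stronger regions. Over the regions with a fold of at least 20, the correlation between the strands was highest at 91 bp with arginine (0.182, against 0.109 when the strands came from different regions) and at 93 bp without arginine (0.309, against 0.179). Averaged over 3 neighbouring distances, the curves had local maxima at 51, 71, 92 and 111 bp in both libraries. The maximum at 111 bp was weak: the correlation there was 0.109 with arginine (0.0870 for strands of different regions) and 0.197 without (0.159), and 1 of these regions in each library had top positions near the summit that lay 110 to 119 bp apart. At 51 bp it was 0.152 (0.126) and 0.248 (0.198). At 82 bp the correlation was 0.139 with and 0.225 without arginine, below the values of 0.167 and 0.260 at 71 bp, where strands of different regions gave 0.126 and 0.198. The distance from the top plus-strand position to the top minus-strand position within 100 bp of the summit had a median of 43 bp over all regions with arginine (quartiles -38.8 and 92) and 53 bp without (quartiles -27.3 and 90). In the regions with a fold of at least 20, the medians were 68 and 71 bp. Of these regions, 23 of 107 with arginine and 16 of 47 without had a distance of 85 to 99 bp. This band was not fixed beforehand and lies around the peaks at 91 and 93 bp in the same regions, so its counts are no separate support for them. Strands taken from different regions gave a mean of 7.71 and a highest value of 14 with arginine, and 4.35 and 9 without. Among all regions, 60 of 490 with arginine and 39 of 206 without had a distance of 85 to 99 bp. For these, strands of different regions gave means of 28.7 and 13.9 and highest values of 44 and 27.

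**Figure D2:**
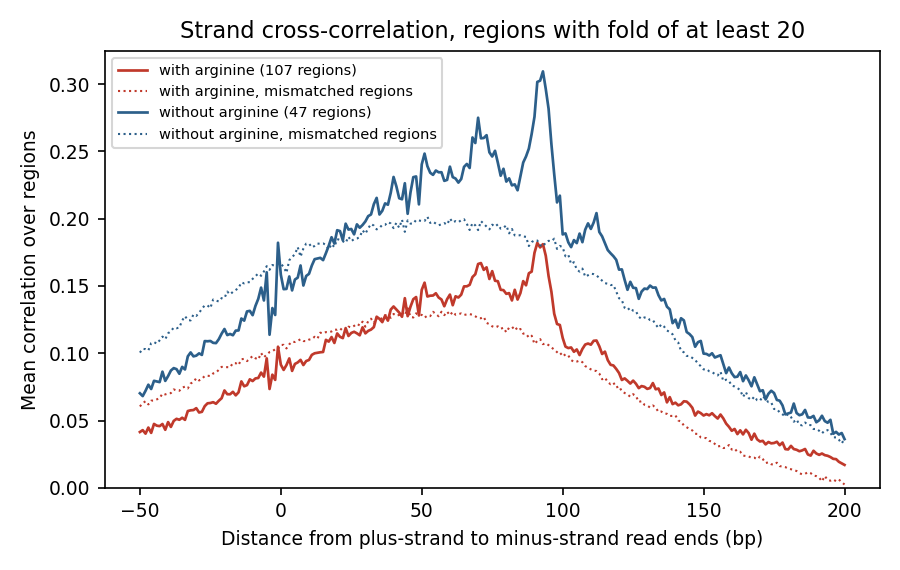
Mean correlation over regions (y axis) between plus-strand and minus-strand read ends at each distance in bp (x axis), for regions with a fold of at least 20 with arginine (107 regions, red) and without (47 regions, blue). Dotted lines pair strands of different regions, and the solid lines peak at 91 bp with arginine and 93 bp without.

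Many of the strongest sites were marked by the same bases in both conditions, and others were not. Of the 24 regions with a fold of at least 200 in either library, 17 had the same top plus-strand position of the whole region in both libraries within 1 bp, and 19 had the same top minus-strand position. In the region 3487351–3488900 the plus strand stopped most often at 3488205 (28687 read ends with and 13965 without arginine) and the minus strand at 3488296 (22520 and 14245), 91 bp apart in both. The region 4151701–4153800 had its top positions at 4152851 and 4152942, also 91 bp apart in both libraries, and 4475401–4477100 at 4476313 and 4476405, 92 bp apart. Shorter distances occurred at other strong regions. In 3315451–3317700 the distance was 47 bp with and 46 bp without arginine, in 28101–30250 it was 54 bp in both, and in 2557551–2558900 it was 40 bp in both. In 2945851–2948400 the plus-strand position 2947207 was shared, while the top minus-strand position was 2947278 with arginine and 2947296 without, so that the distance was 71 bp in the first library and 89 bp in the second. Other strong regions also differed. The region 3295801–3296700 had only 6.58% of its read ends on the plus strand with and 16.5% without arginine, and its top plus-strand positions held 1062 and 963. Both of its top positions moved, and the distance was 92 bp with and 71 bp without arginine. In 3382151–3383100 it was 71 bp with and 81 bp without. In 2087101–2088550 the top minus-strand position lay 188 bp upstream of the top plus-strand position with arginine (-188 bp) and 72 bp downstream without. These are positions of the whole region. Within 100 bp of the summit, both libraries had the same top positions in 2087101–2088550 (-37 bp) and in 2945851–2948400 (18 bp). Among all 111 regions with a fold of at least 20 in either library, 50 shared the top plus-strand position of the whole region, 48 the top minus-strand position and 32 the distance between them.

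**Figure D3:**
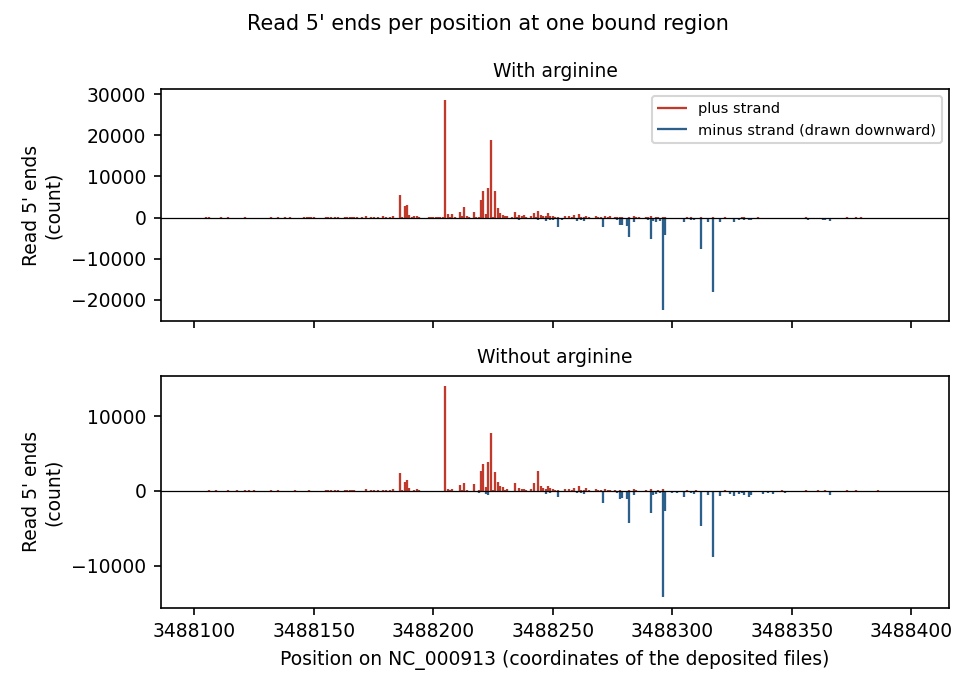
Read 5′ ends per position, as counts (y axis), along part of the region 3487351–3488900 (x axis, position in bp in the coordinates of the deposited files), with arginine (upper panel) and without (lower panel). Plus-strand ends (red) are drawn upward and minus-strand ends (blue) downward; in both panels the tallest bars stand at 3488205 and 3488296.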

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

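The only signal outside the main measurement was a small number of reads listed without a chromosome. There were 55 such reads with arginine and 36 without, above the 3 that a count of 0 allows. They were in no comparison, and their origin was not tested. No group held enough samples to look for an outlying library.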

How the results depend on the processing

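No paired analysis was possible because each file pools the 2 replicates of its condition. For the same reason, leaving out a replicate and fitting a count model were not possible. The alternatives for ARG boxes and known ArgR targets were not run, since they need a sequence or gene positions in the version of the files. Alternatives added after seeing the data were the window highest with arginine, the fold limit of 20 and the top positions of whole regions. So were the same cap in both libraries and the union of regions.

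More regions were called with than without arginine under every setting run, by 1.57 to 2.71 times. The numbers with arginine, without and shared were 1113, 597 and 486 at a fold of 3 with at least 2 on each strand, and 223, 97 and 87 at a fold of 10. They were 916, 338 and 279 with 100 bp windows, and 1173, 749 and 665 without the strand requirement. With a genome-wide background, thinning or a larger overlap, they stayed within 1.5 times the main numbers. The cap on positions left them unchanged, which says little with arginine, where a typical window passes with fewer read ends than a capped position holds. The share of read ends in regions with and without arginine was 68.6% and 54.8% at a fold of 3 with the lower strand limit, 58.2% and 47.6% at a fold of 10, 62.8% and 50.1% with 100 bp windows, 64.2% and 52.1% with a genome-wide background, 48.1% and 34.0% with capped positions, 72.1% and 59.2% without the strand requirement, and 62.3% and 53.5% over the union of regions.

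The median log2 ratio of all regions was 0.26 with total scaling, 0.57 with scaling outside the regions and 0.72 with the same cap in both libraries. In the window of each region that was highest with arginine it was 0.87, a choice of window that favours that library. In regions with a fold of at least 20 in either library it was 1.16. That fold was reached by 107 regions with and 47 without arginine, so this choice also favours the library with arginine. Of the values of named regions, 77 moved beyond rounding without changing sign, 16 did not, and 7 changed sign. With total scaling these were 28101–30250 (-0.027), 2557551–2558900 (-0.14) and 4151701–4153800 (-0.45). The last was -0.15 with scaling outside the regions and -0.069 with the same cap. The region 4475401–4477100 became 0.69 with a cap at the same percentile of each library, and 0.24 with the same cap. The percentile caps were 1139 read ends with and 397 without arginine, so strong regions under them lean toward the ratio of the caps; the same cap was 399.9 and 397 read ends and draws strong regions toward a ratio of 1. The median distance between strands with and without arginine was 40 and 48.5 bp from median positions, and 68 and 71 bp at a fold of at least 20. From top positions of whole regions it was 54.5 bp without arginine. What depth alone limits was tested only by thinning of read ends, which gave 485 regions with arginine and did not match the numbers of occupied positions.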

Other observations

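The cap set alike in both libraries and the tests of depth, of both kinds of pile-up noise, of immunoprecipitation efficiency, of a common efficiency factor and of recurrence on 1 strand were chosen after the result was seen. The tests of copies at single positions and of sequence preference were written before.

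The signal between bound regions was not level along the chromosome, and its shape was alike in both libraries. Among 46 bins of 100 kb, the median window outside the regions was highest at 3300001–3400000 in both, with 191.5 read ends with and 180 without arginine, and lowest at 2300001–2400000, with 99 and 105. The highest bin held the strong regions 3315451–3317700 and 3382151–3383100. By contrast, the bin 2500001–2600000, with the strong region 2557551–2558900, had 107 and 117. Signal beside bound regions was not separated from background, so the shape may hold both. A cosine fitted along the chromosome peaked at 3.92 Mb with and 4.07 Mb without arginine, with a trough at 1.60 and 1.75 Mb. Its peak was 1.19 and 1.20 times its trough, and it took up 15.7% and 24.8% of the variance between bins. Strand bias was also uneven: 32 regions with arginine and 5 without had under 10% of their read ends on 1 strand.

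The region with the largest ratio in favour of the medium without arginine, 364001–364250, had a pair of high positions in that library alone. Its top plus-strand position was 364088 with 154 read ends and its top minus-strand position 364183 with 150 read ends, 95 bp apart. With arginine its highest positions held 12 and 15 read ends. The pair took a large part of the 739 read ends of the region without arginine, and copies of single molecules could not be told apart from repeated stops. Of the regions with a fold of at least 200, 1677201–1677850 had the largest ratio, 5.58 (5.49–5.67) in favour of arginine under the main scaling; it was picked after its values were seen. A single minus-strand position held 29059 of its 96764 read ends with arginine, and 2022 of 17219 without. With the same cap on positions in both libraries its log2 ratio fell from 2.48 to 1.37, below that of 2033251–2033900 (1.89). Its top positions lay 94 bp apart with and 95 bp apart without arginine.

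More regions were called with arginine. Thinning that library to the total of the other left 485 regions against 206, so the total of read ends alone does not account for the difference. The rule divides by each library's own local median, so thinning could change little from the outset. The library with arginine had fewer occupied positions before thinning (798083 against 1389169). Depth in distinct molecules was therefore not matched, and a difference in it stays open. Pile-up noise of that library at unenriched DNA is argued against by the 306 regions called only with arginine, for which the window highest with arginine had a median fold of 3.88 (bootstrap interval 3.55–4.08) in the library without arginine, against 0.972 in windows outside regions. Noise that lifts weakly enriched sites over the limit stays open: the 90th percentile of windows was 3.82 times the median with arginine and 2.80 times without, and this spread also holds binding. The low end, which binding would not lower, also spread wider with arginine. There the 10th percentile was 46 read ends with and 69 without arginine, at medians of 136 and 135. A more efficient immunoprecipitation cannot be told apart from more binding of ArgR with its corepressor, because each condition has 1 pooled library and both would raise the share of read ends in regions, which was 61.7% with arginine.

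The change between conditions was unequal among the 111 regions with a fold of at least 20. The middle 50% of log2 ratios spanned 0.836, against 0.232 for the widest counting interval. That interval leaves out copies made in amplification, so the span does not exclude a common efficiency factor. Copies of single molecules at single positions could add spread: log2 ratios from the plus and the minus strand were related with r = 0.301 across regions (bootstrap interval 0.0778–0.497, Spearman's rho 0.344), which lies between the limits set beforehand and leaves this open. Regions are not independent replicates. A real difference between sites in how far binding depends on arginine is likewise open.

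Read ends often, though not in most of the 111 strong regions, piled up most at the same bases in both conditions. To weigh a sequence preference of ligation, amplification or mapping at any DNA, windows outside the regions were compared. Of these windows 8.41% shared their top position (mean of the strands), against 1.5% by chance. The strong regions were thinned to matched read numbers in up to 20 draws per region, and 39.1% of these draws shared it. Read numbers were matched but molecules were not. Windows outside the regions held 6.79 read ends per occupied position with and 3.22 without arginine, so that copies may set their top position and lower the sharing, and the limit set beforehand does not decide. A sequence preference stays open, as does the hypothesis that the shared bases are borders of the same protein-DNA complex in both media.

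The local maxima of the strand correlation, averaged over 3 neighbouring distances, at 51, 71, 92 and 111 bp lie about 20 bp apart, and a hypothesis was that spacing of repeated contacts along the DNA would also make read ends on 1 strand recur at 19 to 23 bp. The autocorrelation at 19 to 23 bp was above that at 13 to 17 bp and at 25 to 29 bp on 2 of the 4 strands, both without arginine. The autocorrelation falls with distance, which works against such a comparison. The values that were the highest within 6 bp on each side lay at 18 bp on the plus strand with arginine, and at 19 bp on the plus and 21 bp on the minus strand without. The minus strand with arginine had none by this rule, though its value at 21 bp (0.291) stood above those at 20 bp (0.283) and 22 bp (0.272). The rule also returned 10 bp on all 4 strands, the edge of the range searched, although shorter distances within 6 bp gave higher values on each. From 9 to 10 bp the value rose on the minus strand with arginine (0.312 to 0.318). It also rose on both strands without arginine, and not on the plus strand with arginine. A recurrence at 10 bp was not tested. The hypothesis stays open.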
